A study of Homo sapiens with 18 samples.

How the data were processed

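RNA was measured on 18 Agilent 1-colour arrays, 3 for each of 6 groups: non-sorted, ALDH-negative and ALDH-positive cells of the parental and of the radioresistant DU145 line. Group and replicate number came from the sample titles. The submitters' design text speaks of 3 independent experiments, and no label says what a shared replicate number stands for, so p-values measure the spread between these samples.

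The scanner output of each array was used. The authors' scanner software had made, per the file headers, a background-subtracted and detrended spot intensity (gProcessedSignal) with no scaling between arrays, beside the median spot and local background intensity and 0 or 1 flags of other kinds. The software was Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. The deposited table of the whole series held the same intensity rounded to whole numbers, not log2 and not scaled or centred. It lay within 0.5 of the scanner value at every spot and had column medians between 28 and 55. It served as an alternative input.

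Each array held 62976 spots, of which 4259 were controls and were left out, as were the 180 to 522 spots per array marked as outliers. Spots of the same probe were averaged, which left 50599 probes. The main values were log2 of gProcessedSignal minus the 75th percentile of each array. A probe was kept if it was well above background on all 3 arrays of at least 1 group, and 30346 probes were. For 28167 of 29181 RefSeq accessions on the array the gene symbol came from NCBI's annotation of GRCh38.p14, matched without versions; the array design names the build hg19, so no coordinates are given and the annotation served only for names and gene order. In all, 28174 probes had a gene symbol and 22425 had none. The brightest detected probe over all arrays stood for a gene, which gave 15687 genes. Of these 4165 had more than 1 detected probe, and among the changed genes 12, 3 and 12 of the line comparisons (non-sorted, ALDH-negative and ALDH-positive) had another probe that changed the other way, against 0 in either ALDH comparison. Signal over background sets the precision of dim genes, and the number of arrays that of all others. A gene not well above background on any array of a group is given only as a bound.

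Group means were fitted with limma 3.58.1 in R 4.3.3 over all 18 arrays, which share an estimate of the spread, followed by contrasts, eBayes and Benjamini-Hochberg adjustment within each comparison at 0.05. Tables were read with the R package data.table (version 1.17.8), and figures drawn in Python 3.11.15 with matplotlib 3.10.9. Before the data were examined, 35 gene lists with 721 genes, the comparisons, the alternatives and the rule for named genes were fixed. The 33 lists with at least 5 tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Counts of members are given over all genes tested and adjusted over the list alone.

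Named genes were, for the line and ALDH comparisons, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and which were well above background on all arrays of at least 1 group, only with proper gene symbols. To these came up to 4 members with the smallest adjusted p of each list described, and ALDH1A1, ALDH1A3, ALDH2, ALDH3A1, ALDH7A1, CD44, MYC and CTNNB1. For the interaction and the sort comparisons the rule took 5 and 5 called genes, of which there were 0. Genes outside the rule are said to be chosen after their values were seen. CTNNB1, ALDH3A1 and ALDH7A1 did not pass in limma in any line comparison (smallest adjusted p 0.457, 0.0845 and 0.227). Of the genes the rule named, 5 are not reported here by name, and they stayed in the counts and list tests.

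Pairing was checked from the replicate numbers in the titles. Between ALDH-positive and ALDH-negative arrays with the same number, the correlation of deviations from the group means was 0.42, 0.38 and 0.35 in the parental and 0.66, 0.48 and 0.58 in the radioresistant line, all over the limit of 0.1, so these comparisons are also given with the number as a block. In the line and the sort comparisons the limit was not met by all pairs.

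Alternatives were median scaling, quantile normalization, normexp background correction, the deposited table, outlier spots kept, no detection filter, detection on all 18 arrays, the mean of a gene's probes, each probe alone, the replicate number as a block, slide and scan as a block or a random block, a fit of the groups compared alone, a variance trend with robust fitting, a 2-fold threshold and each array left out. Normexp (offset 50) was run on the median spot and background intensity, since the mean was not used here. Alternatives added after seeing the data were a block for each replicate number within each line, each slide alone (groups with 1 array there are assumed to vary like the others), the replicate and slide blocks together, ALDH-negative against non-sorted cells, and the other scalings for the gene lists.

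The code was tested on simulated data with 50 of 15687 genes changed at each fold and the spread of the real arrays. For the radioresistant ALDH comparison limma recovered 18% of genes changed 1.5-fold, 54% at 2-fold, 96% at 3-fold and 94% at 4-fold, with 10 false calls among 141. For the non-sorted line comparison it recovered 20%, 66%, 90% and 94%, with 9 false calls among 144, and for the interaction 2%, 34%, 68% and 78%, with 6 among 97. For the radioresistant ALDH comparison camera found the 1 raised list and called 0 of 20 unchanged lists, with gene correlation untested.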

Results

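The series measured RNA levels in DU145, an established human prostate cancer cell line first grown from a brain metastasis, and in a radioresistant sub-line made from it by repeated X-ray doses of 4 Gy with 1 week of recovery after each. Cells of both lines were taken non-sorted, or were stained with Aldefluor and sorted by flow cytometry into ALDH-positive and ALDH-negative cells. Aldefluor is a substrate that aldehyde dehydrogenases turn into a fluorescent product held inside the cell. This gave 6 groups of 3 arrays, 18 arrays in all, each hybridised with a Cy3-labelled sample made from 50 ng of RNA. The series title sets radioresistant cells beside progenitor cells. The design poses 8 comparisons: the radioresistant against the parental line in each of the 3 populations, ALDH-positive against ALDH-negative cells in each line, the interaction of line and ALDH population, and sorted against non-sorted cells in each line. Changes are log2 differences ± standard error from limma with 3 arrays per group, and the precision is limited by the number of arrays.

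Between 27779 and 32901 of the 50599 probes were well above background on each array (54.9% to 65.0%), and 0 probes were saturated. In all, 15687 genes were tested, and 14138 of them were well above background on all 18 arrays. Correlations of log2 levels across genes, which are not independent replicates, lay between 0.977 and 0.995 for arrays of the same group and between 0.948 and 0.967 for arrays of different lines. The first principal component held 55.6% of the variance and parted the lines. The second held 8.73% and parted the replicate numbers, with all arrays numbered 3 between -35.9 and -13.1 and all others between -2.05 and 28.1. The arrays lay on 3 slides of 6. Slide 1 held all parental non-sorted and parental ALDH-negative arrays and no others. The parental ALDH-positive and all radioresistant arrays were spread over slides 2 and 3.

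**Figure D1:**
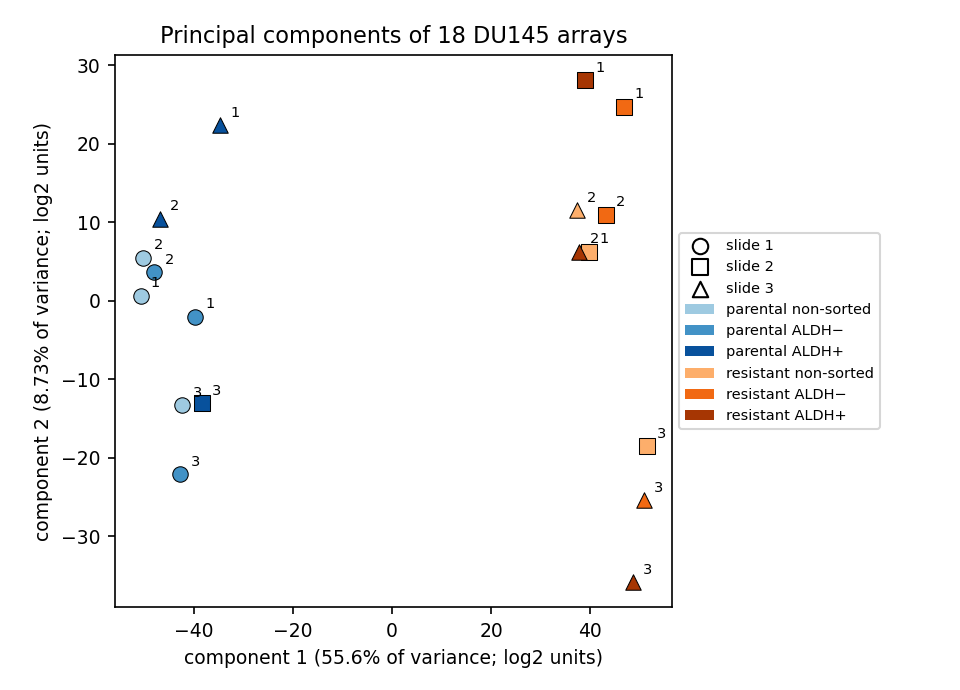
First and second principal components of the log2 levels of the tested genes on the 18 arrays, with each point an array, its colour the group, its shape the slide, the digit its replicate number, and the share of variance on each axis. The first component (55.6% of the variance) parts parental from radioresistant arrays, and arrays with the number 3 lie lowest on the second (8.73%).

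In non-sorted cells, the radioresistant line had 107.2-fold more CCL2, the chemokine that attracts monocytes, with a mean log2 level of 2.14 ± 0.18 (SD, n = 3) against -4.60 ± 0.31 (SD, n = 3) in the parental line. That rise of 6.74 ± 0.41 had an adjusted p of 4.5e-08 in limma, and CCL2 was well above background on 2 of the 3 parental arrays. GJA1, the gap junction protein connexin 43, was at least 41.1-fold higher, FGF13 at least 18.1-fold, and IL7R, the receptor chain for interleukin 7, at least 24.5-fold. S1PR3, a receptor for sphingosine 1-phosphate, was at least 58.4-fold lower, the filopodia-associated FAM110C at least 49.6-fold and NPTX2, a neuronal pentraxin, at least 39.0-fold. Such a bound sets the mean of the brighter group against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. In total 4593 genes changed in limma, 2290 up and 2303 down, and 861 rose and 665 fell by at least 2-fold.

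Among the other large rises in non-sorted cells were MAP2, a microtubule protein of neurons, by 6.25 ± 0.55 (above background on 2 of the 3 parental arrays), the acetyltransferase-like NAT16 by 5.26 ± 0.31, and DMBT1, a secreted scavenger receptor, by 5.18 ± 0.46 (1 of the 3 parental arrays). AKR1B15, an aldo-keto reductase, rose by 5.10 ± 0.71, and its probe may also read its close copy AKR1B10. Among the falls, TM4SF19 changed by -6.28 ± 0.76 (above background on 1 of the 3 radioresistant arrays) and NPR3, the clearance receptor for natriuretic peptides, by -6.25 ± 0.95 (2 of the 3). The non-coding RNA CEROX1 was at least 14.9-fold lower, DRC11, a part of motile cilia, at least 15.2-fold and the protocadherin PCDHB5 at least 15.5-fold. Adjusted p in limma ran from 4.69e-10 for CEROX1 to 2.68e-04 for GJA1 over these 16 genes. The parental arrays all lay on slide 1 and the radioresistant ones on slides 2 and 3; with slide as a random block limma called 4646 genes. With median scaling, which moved the median of all genes from -0.01 to -0.13, it called 4425 genes, of which 1584 rose (35.8% against 49.9%).

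ALDH-negative cells of the radioresistant line differed from parental ALDH-negative cells in 4866 genes in limma, 2699 up and 2167 down, with 833 rises and 752 falls of at least 2-fold. MAP2 rose by 6.43 ± 0.55 (above background on 2 of the 3 parental arrays) and CCL2 was at least 71.5-fold higher. NAT16 rose by 5.34 ± 0.31, and ENPP2, the enzyme autotaxin that makes lysophosphatidic acid, by 5.24 ± 0.56 (1 of the 3 parental arrays). TXNIP, which binds and inhibits thioredoxin, rose by 5.23 ± 0.62, and the proprotein convertase PCSK5 was at least 8.49-fold higher. The pseudogenes GGT8P, up by 5.48 ± 0.18 with the smallest adjusted p (5.29e-11), and CCNYL4, at least 9.82-fold higher, have near-identical copies, so which gene was read stays uncertain. S1PR3 was at least 44.6-fold lower, PGAP4, a Golgi enzyme of GPI anchor processing, at least 46.3-fold, NPTX2 at least 39.9-fold and FAM110C at least 39.5-fold. CEROX1 was at least 14.2-fold and the leukocyte receptor gene VSTM1 at least 13.3-fold lower, while NPR3 changed by -6.76 ± 0.95 (2 of the 3 radioresistant arrays above background) and TM4SF19 by -5.32 ± 0.76 (1 of the 3). The same split over slides held here, and a random slide block, which cannot remove a shift of slide 1, gave 4904 genes.

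ALDH-positive cells of the radioresistant line differed from parental ALDH-positive cells in 4094 genes in limma, 1871 up and 2223 down, with 661 rises and 703 falls of at least 2-fold. MAP2 rose by 6.01 ± 0.55 (above background on 2 of the 3 parental arrays), CCL2 by 5.84 ± 0.41, and AKR1C1, an aldo-keto reductase that inactivates progesterone, by 5.10 ± 0.56 (2 of the 3 parental arrays; close copies in the AKR1C family leave the gene uncertain). GGT8P rose by 4.82 ± 0.18 and ENPP2 by 4.72 ± 0.56 (1 of the 3 parental arrays). NPNT, an extracellular matrix ligand of integrins, was at least 17.2-fold higher, CCNYL4 at least 8.96-fold and FGF13 at least 6.74-fold. FAM110C was at least 36.2-fold lower, VSTM1 at least 32.9-fold, S1PR3 at least 27.4-fold, NPTX2 at least 18.3-fold, CEROX1 at least 17.1-fold and PCDHB5 at least 13.1-fold. NPR3 changed by -5.78 ± 0.95 (2 of the 3 radioresistant arrays) and PGAP4 by -5.40 ± 0.36 (1 of the 3). Here both lines lay on slides 2 and 3: limma called 3337 genes with slide as a block, 54 on slide 2 alone (1 array of each line, assumed to vary like the other groups on that slide) and 904 on slide 3 alone (2 of each line), and 491 with scan as a block, where 2 of the radioresistant arrays had a scan to themselves. With median scaling, which moved the median of all genes from -0.04 to 0.12, 2733 of 3879 called genes rose (70.5% against 45.7%), and a spread estimated from these 6 arrays alone gave 1891 genes.

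The 3 line comparisons share no arrays. Of the 6684 genes that limma called in any population, 1337 rose and 1309 fell in all 3, which is 39.6%, and 7 were called in opposite directions. The log2 changes correlated across genes, which are not independent replicates, at r = 0.918 (Spearman 0.875) between non-sorted and ALDH-negative cells, 0.834 (0.739) between non-sorted and ALDH-positive cells, and 0.832 (0.747) between the ALDH-negative and ALDH-positive cells. Non-sorted and ALDH-negative cells shared 1845 risen and 1670 fallen genes, where independent lists would share 394 and 318. Genes whose 3 parental and 3 radioresistant levels did not overlap made up 48.7% of the tested genes in non-sorted, 45.8% in ALDH-negative and 35.3% in ALDH-positive cells, against 10% by chance.

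Targets of NRF2, the transcription factor that induces antioxidant and detoxifying enzymes, were higher as a list in the radioresistant line at camera's preset correlation. Of the 23 tested, 14 rose in non-sorted, 15 in ALDH-negative and 14 in ALDH-positive cells, and 0 fell (16, 16 and 14 rose adjusted over the list alone). The list's median change was 0.83, 0.81 and 0.76 in that order, with adjusted p = 3.76e-06, 5.03e-06 and 4.51e-08 in camera. With an estimated correlation the adjusted p = 0.343, 0.681 and 0.421 in camera. With slide as a block the median in ALDH-positive cells was 0.76, on slide 2 alone 0.62 and on slide 3 alone 0.78. The export pump ABCC2 rose by 3.43 ± 0.35, 3.21 ± 0.35 and 3.31 ± 0.35, and AKR1C1 by 4.25 ± 0.56, 4.68 ± 0.56 and 5.10 ± 0.56 (above background on 3, 2 and 2 of the 3 parental arrays). GCLC, the catalytic part of the enzyme that starts glutathione synthesis, rose by 1.74 ± 0.25 and AKR1B10 by 4.93 ± 0.69 in non-sorted cells. TKT, transketolase of the pentose phosphate pathway, rose by 1.19 ± 0.12 and the ferritin light chain FTL by 1.36 ± 0.15 in ALDH-negative cells.

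**Figure D2:**
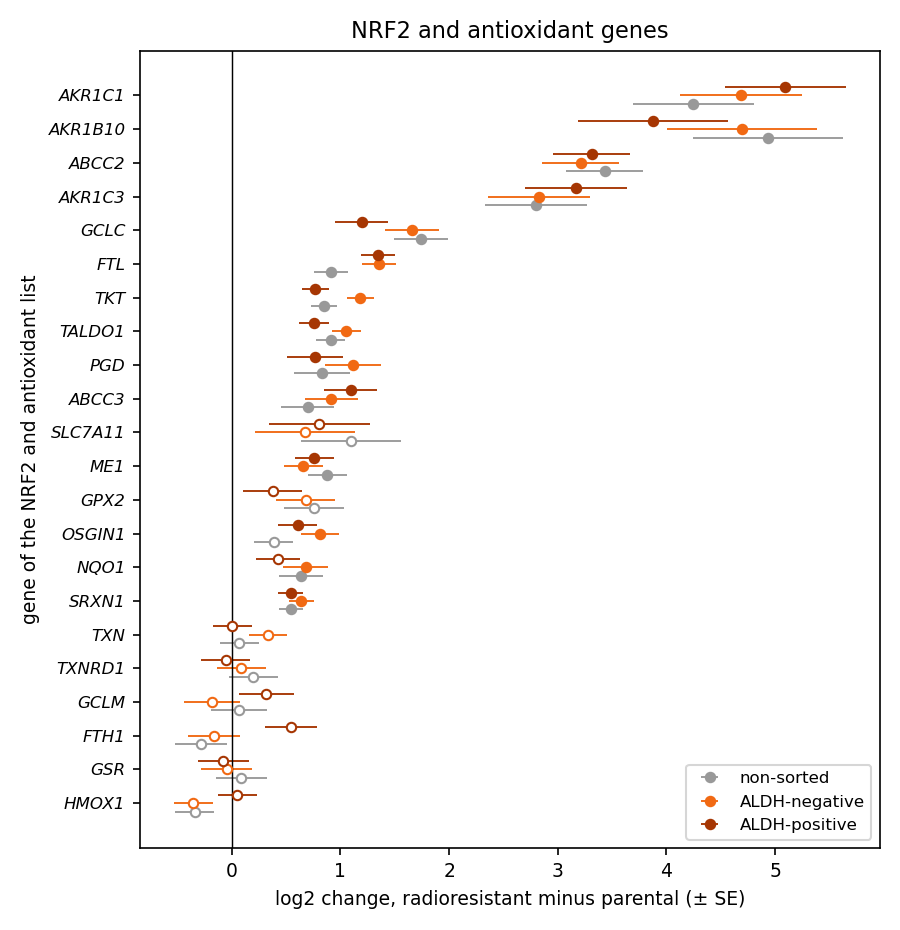
Log2 change between the radioresistant and the parental line of 22 of the 23 tested NRF2 target genes in non-sorted, ALDH-negative and ALDH-positive cells, with each point a gene's estimate from limma and its bar the standard error (3 arrays per group), filled where limma called the gene. In each population 0 of the 23 genes fell, and the largest rises are those of AKR1B10, AKR1C1 and ABCC2.

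Of 20 tested NF-kappaB target genes and cytokines, 2 rose and 9 fell in non-sorted radioresistant cells, and 2 rose and 10 fell in both sorted populations (2 and 11 adjusted over the list alone in each). CCL2 was among those that rose. CSF2, the cytokine GM-CSF, changed by -3.39 ± 0.22, -3.54 ± 0.22 and -2.12 ± 0.22 in non-sorted, ALDH-negative and ALDH-positive cells. ICAM1, an adhesion molecule for leukocytes, changed by -2.29 ± 0.16, -2.08 ± 0.16 and -2.02 ± 0.16. The chemokine CXCL1 changed by -2.59 ± 0.36 in non-sorted and -2.89 ± 0.36 in ALDH-negative cells, and BIRC3, an inhibitor of apoptosis, by -2.34 ± 0.29 in ALDH-positive cells. The list's medians were -0.90, -0.76 and -0.84, with adjusted p = 0.00577, 0.00159 and 0.0427 in camera, and adjusted p = 0.863, 0.681 and 0.810 with an estimated correlation in camera. Without radioresistant ALDH-negative replicate 3 the median in ALDH-negative cells was -1.18. In ALDH-positive cells the median was -0.84 with slide as a block, -1.56 on slide 2 alone and -0.46 on slide 3 alone, and the call was lost with quantile normalization (0.0540), with the replicate number as a block (0.0667) and on slide 3 (0.353). It was also lost in camera without parental ALDH-positive replicate 3 (0.124) or without the radioresistant ALDH-positive replicate 1 (0.139), ALDH-positive replicate 2 (0.0540) or non-sorted replicate 3 (0.0605).

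Mesenchymal genes were higher as a list in the radioresistant line, led by SNAI2, a repressor of epithelial genes, which rose by 3.23 ± 0.43, 2.91 ± 0.43 and 2.62 ± 0.43 in non-sorted, ALDH-negative and ALDH-positive cells (above background on 3, 2 and 3 of the 3 parental arrays). ACTA2, smooth muscle actin, rose by 1.51 ± 0.35, 1.48 ± 0.35 and 1.69 ± 0.35, and SNAI1, a relative of SNAI2, by 0.55 ± 0.12 in non-sorted and 0.96 ± 0.12 in ALDH-negative cells. Of 19 tested genes, 7, 6 and 6 rose (8, 7 and 6 adjusted over the list alone). The medians were 0.49, 0.35 and 0.41, with adjusted p = 0.0385, 0.0432 and 0.0407 in camera, and adjusted p = 0.343, 0.681 and 0.421 with an estimated correlation in camera. In non-sorted cells the median was 0.318 with normexp background, and the call was lost with quantile normalization (0.0676) and without parental non-sorted replicate 2 (0.0532) or radioresistant non-sorted replicate 2 (0.0608). In ALDH-negative cells camera lost it without parental ALDH-negative replicate 1 (0.0789) or 2 (0.0576), or without the radioresistant ALDH-negative replicate 3 (0.0650), non-sorted replicate 3 (0.0548) or ALDH-positive replicate 1 (0.0503). For ALDH-positive cells the median was 0.41 with slide as a block, 0.62 on slide 2 alone and 0.32 on slide 3 alone, and camera lost the call with median scaling (0.0736), on slide 3 (0.106), and without parental ALDH-positive replicate 3 (0.0709) or the radioresistant ALDH-positive replicates 1 (0.0659) and 2 (0.0555) or non-sorted replicate 3 (0.0530).

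Genes of the G2 and M phases were lower as a list in the radioresistant line in non-sorted and ALDH-negative cells. Of 27 tested, 10 and 6 fell (15 and 6 adjusted over the list alone), with medians of -0.59 and -0.48 and adjusted p = 4.13e-05 and 6.66e-04 in camera, and adjusted p = 0.863 and 0.907 with an estimated correlation in camera. BUB1B, a spindle checkpoint kinase, changed by -1.13 ± 0.20 and -0.98 ± 0.20, CDK1, the kinase that drives entry into mitosis, by -0.81 ± 0.16 and -0.98 ± 0.16, and the kinesin KIF23 by -1.08 ± 0.27 and -1.14 ± 0.27. In ALDH-positive cells 1 of the 27 rose (the checkpoint kinase TTK, by 0.46 ± 0.16, not called in limma without parental ALDH-positive replicate 1 or 2 or radioresistant ALDH-positive replicate 1 or 2, at 0.138, 0.106, 0.137 and 0.0694), 0 fell, and the list did not pass (median -0.18, adjusted p = 0.430 in camera). On slide 2 alone that median was 0.35 and the list did not pass, and on slide 3 alone it was -0.46 and passed in camera (0.0224). Of 25 genes of the G1 to S transition, 4, 8 and 1 fell and 0, 0 and 1 rose in non-sorted, ALDH-negative and ALDH-positive cells (3, 8 and 0 fell adjusted over the list alone). That list passed in ALDH-negative cells, with a median of -0.355 and adjusted p = 0.0013 in camera (adjusted p = 0.907 with an estimated correlation), and did not in non-sorted (0.179) and ALDH-positive cells (0.541). Without radioresistant ALDH-negative replicate 3 the medians in ALDH-negative cells were -0.146 for this list and -0.302 for the G2 and M list. In ALDH-negative cells FEN1, a flap endonuclease of DNA replication, changed by -1.11 ± 0.16, the ribonucleotide reductase subunit RRM2 by -1.23 ± 0.26 and ORC1, of the origin recognition complex, by -1.23 ± 0.29. Whether the lists' line changes differ between ALDH populations is tested by the interaction of line and ALDH population.

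Of 33 tested genes of DNA double-strand break repair, 1 rose and 10 fell in non-sorted, 2 rose and 12 fell in ALDH-negative and 1 rose and 8 fell in ALDH-positive radioresistant cells. CHEK1, a kinase of the DNA damage checkpoint, changed by -1.19 ± 0.16, -1.20 ± 0.16 and -1.04 ± 0.16 in that order. RBBP8, which starts the resection of broken ends, changed by -0.63 ± 0.12 in ALDH-negative and -0.60 ± 0.12 in ALDH-positive cells. The helicase BLM changed by -1.21 ± 0.24 in non-sorted and -1.58 ± 0.24 in ALDH-negative cells, and the recombination protein RAD54L by -1.51 ± 0.27 in ALDH-negative cells, while XRCC1, a scaffold of single-strand break repair, rose by 0.58 ± 0.12 in ALDH-positive cells. The list passed in ALDH-negative cells (2 rose and 13 fell adjusted over the list alone), with a median of -0.27 and adjusted p = 0.00235 in camera, and adjusted p = 0.681 with an estimated correlation. It did not pass in non-sorted (adjusted p = 0.0802 in camera; 0.0454 without radioresistant non-sorted replicate 1) or ALDH-positive cells (0.0863).

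Genes of cholesterol synthesis were lower as a list in both sorted populations of the radioresistant line. Of 21 tested, 8, 7 and 9 fell in non-sorted, ALDH-negative and ALDH-positive cells and 0 rose. STARD4, a carrier of sterols, changed by -1.50 ± 0.24, -2.03 ± 0.24 and -1.31 ± 0.24, and HMGCS1, of the mevalonate pathway, by -1.08 ± 0.19 in ALDH-negative and -1.18 ± 0.19 in ALDH-positive cells. The medians were -0.28 in ALDH-negative and -0.55 in ALDH-positive cells, with adjusted p = 0.0240 and 0.00888 in camera, and adjusted p = 0.905 and 0.744 with an estimated correlation in camera. The call in ALDH-negative cells was lost without parental ALDH-negative replicate 1 (0.125, median -0.156), and that in ALDH-positive cells without parental ALDH-positive replicate 1 (0.0756, median -0.31) or radioresistant ALDH-positive replicate 1 (0.0518). Without radioresistant ALDH-negative replicate 1 the median in ALDH-negative cells was -0.168. In ALDH-positive cells the median was -0.30 on slide 2 alone (1 array of each line) and -0.52 on slide 3 alone. It was -0.55 with slide as a block and -0.347 with normexp background there. In non-sorted cells camera's adjusted p was 0.0570, and without parental non-sorted replicate 3, radioresistant non-sorted replicate 1 or radioresistant ALDH-positive replicate 1 it was 0.0298, 0.0227 and 0.0482.

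Of 28 tested ribosomal protein genes 14 rose and 0 fell in ALDH-negative cells of the radioresistant line (15 rose adjusted over the list alone). RPL15 rose by 1.05 ± 0.17, RPL32 by 0.96 ± 0.17 and RPS6 by 0.91 ± 0.19 there. In ALDH-positive cells 5 rose (4 adjusted over the list alone), and in non-sorted cells 3 rose and 1 fell. The medians were 0.46 in ALDH-negative and 0.26 in ALDH-positive cells, with adjusted p = 0.0013 and 0.0352 in camera, and adjusted p = 0.907 and 0.819 with an estimated correlation in camera. Quantile normalization ended both calls (0.101 and 0.831), with medians of 0.252 and 0.000454, and median scaling gave a median of 0.429 in ALDH-positive cells. Among ALDH-positive cells the ribosomal median was 0.26 with slide as a block, 0.48 on slide 2 alone and 0.11 on slide 3 alone, and camera's call was also lost with normexp background (0.0511), on slide 3 (0.128) and without parental ALDH-positive replicate 2 (0.0750) or radioresistant ALDH-positive replicate 1 (0.139, median 0.112). The list did not pass in non-sorted cells (adjusted p = 0.204 in camera; 0.0298 without parental non-sorted replicate 3).

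Of 15 tested aldehyde dehydrogenase genes, the family whose activity the stain reads, 5 rose in non-sorted, 6 in ALDH-negative and 4 in ALDH-positive radioresistant cells, and 1 fell in the last (5, 6 and 5 rose adjusted over the list alone). ALDH3A2, which oxidises fatty aldehydes, rose by 0.83 ± 0.13, 0.97 ± 0.13 and 0.70 ± 0.13, and the mitochondrial ALDH1L2 by 1.35 ± 0.25, 1.30 ± 0.25 and 0.95 ± 0.25 (the last not called without parental ALDH-positive replicate 2, limma adjusted p = 0.0552). ALDH2, which clears acetaldehyde, rose by 0.86 ± 0.22 in ALDH-negative cells (limma adjusted p = 0.00845). ALDH1A3, which makes retinoic acid, changed by -0.51 ± 0.22 (limma adjusted p = 0.0871), 0.08 ± 0.22 (0.810) and -0.83 ± 0.22 (0.0104); without parental or radioresistant ALDH-positive replicate 2 the last was 0.0573 and 0.0515. ALDH1A1 changed by 0.52 ± 0.24 (0.127), 0.75 ± 0.24 (0.0290) and 0.55 ± 0.24 (0.111) in limma, and without parental ALDH-negative replicate 1 or radioresistant ALDH-negative replicate 1 or 2 its adjusted p in ALDH-negative cells was 0.130, 0.0945 and 0.0689. The list did not pass in camera (adjusted p = 0.250, 0.180 and 0.0863; 0.0450 in ALDH-negative cells without parental ALDH-negative replicate 3), and its median in non-sorted cells was 0.12, or -0.0008 with median scaling.

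CD44, a hyaluronan receptor often used as a stem cell marker, rose by 1.47 ± 0.23, 1.41 ± 0.23 and 1.07 ± 0.23 in non-sorted, ALDH-negative and ALDH-positive radioresistant cells (limma adjusted p = 2.37e-04, 3.04e-04 and 0.00298). NES, the neural progenitor filament nestin, rose by 1.08 ± 0.16, 0.77 ± 0.16 and 1.20 ± 0.16. The integrin subunit ITGA2 changed by -2.98 ± 0.54 in ALDH-negative and -2.92 ± 0.54 in ALDH-positive cells (above background on 1 of 3 radioresistant arrays in each). Of 16 tested stem cell markers 4, 3 and 3 rose and 3, 4 and 5 fell, and the list did not pass in camera (adjusted p = 0.730, 0.964 and 0.869). Of 19 tested Wnt target genes 6, 5 and 4 rose and 5, 4 and 5 fell. Among these, LEF1, a transcription factor of the Wnt pathway, rose by 3.62 ± 0.49 in non-sorted and 3.10 ± 0.49 in ALDH-positive cells (1 and 2 of 3 parental arrays above background) and was at least 6.36-fold higher in ALDH-negative cells. RNF43, which removes Wnt receptors from the surface, changed by -2.68 ± 0.52, -3.11 ± 0.52 and -3.07 ± 0.52 (above background on 3, 2 and 3 radioresistant arrays). MYC rose by 0.62 ± 0.17 (0.0108) and 0.65 ± 0.17 (0.00783) and differed by 0.28 ± 0.17 (0.233) in limma, with an adjusted p of 0.0511 in non-sorted cells without radioresistant non-sorted replicate 2.

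Epithelial genes went both ways between the lines. Of 21 tested, 5 rose and 5 fell in non-sorted, 6 rose and 5 fell in ALDH-negative and 2 rose and 10 fell in ALDH-positive cells. CLDN4, a tight junction claudin, rose by 4.15 ± 0.20, 4.45 ± 0.20 and 3.76 ± 0.20. EPCAM, an epithelial adhesion molecule, changed by -1.33 ± 0.22 in non-sorted and -2.51 ± 0.22 in ALDH-positive cells. In ALDH-positive cells the tight junction scaffold TJP1 changed by -1.19 ± 0.22 and the keratin KRT18 by -0.90 ± 0.18. The list did not pass in camera (adjusted p = 0.761, 0.883 and 0.0648), and without parental or radioresistant ALDH-positive replicate 2 the last was 0.0242 and 0.0182. Of 9 basal prostate genes 2, 3 and 5 fell and 1, 1 and 0 rose. ITGB4, the integrin of hemidesmosomes, changed by -1.68 ± 0.36 in ALDH-positive cells. In ALDH-positive cells the basal list had a median of -0.69 and adjusted p = 0.0648 in camera, or 0.0274 and 0.0426 without parental or radioresistant ALDH-positive replicate 2. Of 11 leukocyte markers, a check for other cells, 2, 2 and 2 rose and 1, 0 and 2 fell with adjusted p = 0.761, 0.964 and 0.869 in camera, and of 6 erythroid markers 0 passed in limma, with adjusted p = 0.950, 0.964 and 0.869 for the list in camera.

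**Figure D3:**
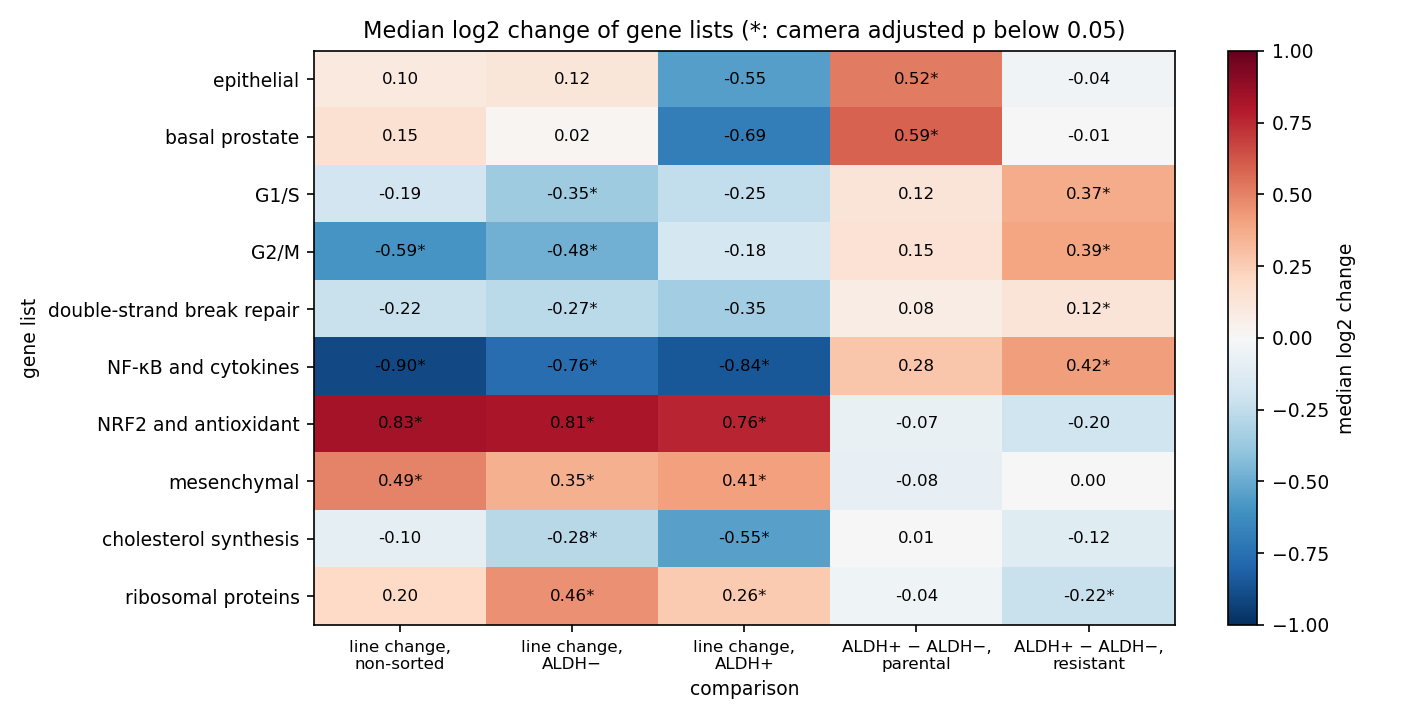
Heat map of the median log2 change of the tested members of 10 fixed gene lists (one line of cells per list) in the 3 line comparisons and both ALDH comparisons, from red for higher to blue for lower, with the median printed and an asterisk where camera's adjusted p at its preset correlation was below 0.05 (3 arrays per group). NRF2 targets lie at 0.83, 0.81 and 0.76 in the 3 line comparisons, and NF-kappaB targets at -0.90, -0.76 and -0.84.

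ALDH-positive parental cells had more EPCAM, BMPER, ALDH1A3 and SH2D3A than ALDH-negative parental cells. EPCAM rose by 1.81 ± 0.22 (limma adjusted p = 0.00614), from a mean log2 level of 2.69 ± 0.31 to 4.495 ± 0.24 (SD, n = 3). ALDH1A3 was the member of the stained enzyme family that rose, by 1.55 ± 0.22 (0.0153 in limma), from 2.54 ± 0.19 to 4.09 ± 0.25 (SD, n = 3). BMPER, a secreted modulator of BMP signalling, rose by 1.64 ± 0.23 (0.0153 in limma) and the adaptor protein gene SH2D3A by 0.96 ± 0.14 (0.0245). These 4 were all the genes that limma called, with 0 falls, while 1175 had an unadjusted p under 0.05, where 784 would be expected by chance. The number 1 to 3 paired ALDH-positive with ALDH-negative samples. With the replicate number as a block limma called 12 genes, 8 up and 4 down, and all 4 were among them; with a block for each number within each line it called 0, and the adjusted p was 0.0571 for EPCAM and ALDH1A3, 0.0604 for BMPER and 0.0631 for SH2D3A. Median scaling, which moved the median of all genes from 0.02 to -0.11, gave 0 genes. Without ALDH-negative replicate 1 or 3 or ALDH-positive replicate 1 limma called 0, without ALDH-negative replicate 2 it called 2 and without ALDH-positive replicate 2 it called 1. ALDH1A3 was called with all arrays and without ALDH-positive replicate 3, and its adjusted p was at most 0.0962 without any other of the 6. The 3 ALDH-negative arrays lay on slide 1 and the ALDH-positive ones on slides 2 and 3, so no slide held both groups. A random slide block gave 9 genes, but it cannot remove a shift of slide 1.

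All 21 tested epithelial genes lay higher in ALDH-positive than in ALDH-negative parental cells, with a median of 0.52 and adjusted p = 8.2e-15 in camera (adjusted p = 0.0114 with an estimated correlation). Of these 1 rose by the test over all genes, EPCAM, and 12 adjusted over the list alone. CDH1, the adhesion molecule E-cadherin, differed by 2.21 ± 0.49 (0.204 in limma), OVOL2, a regulator of epithelial genes, by 1.77 ± 0.46 (0.286) and the membrane protease ST14 by 0.62 ± 0.20 (0.441). Of 9 basal prostate genes 0 rose over all genes and 3 adjusted over the list alone, with a median of 0.59 and adjusted p = 4.72e-04 in camera (adjusted p = 0.0363 with an estimated correlation). The basal median was 0.392 with normexp background and 0.393 without ALDH-negative replicate 1. COL17A1, a collagen of hemidesmosomes, differed by 0.92 ± 0.17 (0.0767 in limma) and ITGB4 by 1.72 ± 0.36 (0.158). With a block for each number within each line and an estimated correlation, camera's adjusted p was 0.687 for both lists. With the replicate block 3 further lists passed camera: stem cell markers (0.0496 against 0.0620 unblocked), G1 to S genes (0.0329 against 0.0620) and G2 and M genes (0.0496 against 0.0724). With an estimated correlation their adjusted p was 0.495, 0.770 and 0.777 in camera. Unblocked, the stem cell list passed without ALDH-negative replicate 3 (0.00923) or ALDH-positive replicate 1 (0.0292). The G1 to S list did so without ALDH-negative replicate 2 (0.00461) or ALDH-positive replicate 1 (0.0171), and the G2 and M list without those same arrays (0.0194 and 0.00520). With a block for each number within each line camera passed G1 to S genes (0.0173), hypoxia and glycolysis genes (0.0173) and NF-kappaB targets (0.0194) but not stem cell markers (0.0693) or G2 and M genes (0.0829), and with an estimated correlation each of these 5 lists had 0.701. Unblocked, the hypoxia list passed without ALDH-positive replicate 1 (0.0497) or 2 (0.0306), and NF-kappaB targets without ALDH-negative replicate 2 (0.0194) or 3 (0.00150), ALDH-positive replicate 1 (7.8e-04) or radioresistant ALDH-negative replicate 1 (0.0463). Of the 15 aldehyde dehydrogenase genes 1 rose, and the family as a list did not pass (adjusted p = 0.509 in camera). ALDH1A1 differed by 0.13 ± 0.24 (0.954 in limma), ALDH2 by 0.00 ± 0.22 (0.999), ALDH3A1 by -0.94 ± 0.29 (0.421), ALDH7A1 by -0.29 ± 0.22 (0.820), CD44 by 0.39 ± 0.23 (0.752) and MYC by 0.15 ± 0.17 (0.902).

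ALDH-positive radioresistant cells had more CDK1 and CSF2 than ALDH-negative radioresistant cells. CDK1 rose by 1.52 ± 0.16 (limma adjusted p = 0.00118) and CSF2 by 1.54 ± 0.22 (0.0145). The cell cycle transcription factor E2F8 rose by 1.22 ± 0.19 (0.0360 in limma), the spindle protein CKAP2L by 0.97 ± 0.16 (0.0464) and C2CD4C by 0.70 ± 0.11 (0.0360). The proteoglycan biglycan, BGN, was at least 1.99-fold lower (0.0360 in limma), and TCP10L changed by -1.11 ± 0.15 (0.0145) and the non-coding ZNF503-AS2 by -0.73 ± 0.11 (0.0195). ALDH1A3 differed by 0.63 ± 0.22 (0.391 in limma), ALDH1A1 by -0.07 ± 0.24 (0.970), CD44 by 0.05 ± 0.23 (0.981) and MYC by -0.22 ± 0.17 (0.793). Limma called these 8 genes, 5 up and 3 down, with 1266 at an unadjusted p under 0.05.

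The numbers paired these samples too, and the blocked counts were higher: 78 genes (66 up and 12 down) with the replicate number as a block and 200 (156 up and 44 down) with a block for each number within each line, of which 64 were shared and all 8 unblocked genes were in both. HJURP, which loads the centromere histone, rose by 1.24 under the replicate block (limma adjusted p = 0.00100 against 0.116 unblocked), and CENPA, that histone, by 0.87 (0.00725); HJURP was chosen after its values were seen. Slide as a block gave 2 genes, scan as a block 0, the replicate and slide blocks together 0, and slides 2 and 3 alone 0 each. Limma called 27 genes with quantile normalization, 5 with median scaling, and 0 with a spread from these 6 arrays alone. It called 1 gene without ALDH-negative replicate 1 or ALDH-positive replicate 2, 4 without ALDH-negative replicate 3 and 14 without ALDH-positive replicate 1. CDK1 was called by limma without each of the 6 arrays in turn, and each of the other 7 genes lost its call without at least 2 of them, as CSF2 did without ALDH-negative replicate 1 (0.105) or ALDH-positive replicate 2 (0.0674).

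**Figure D4:**
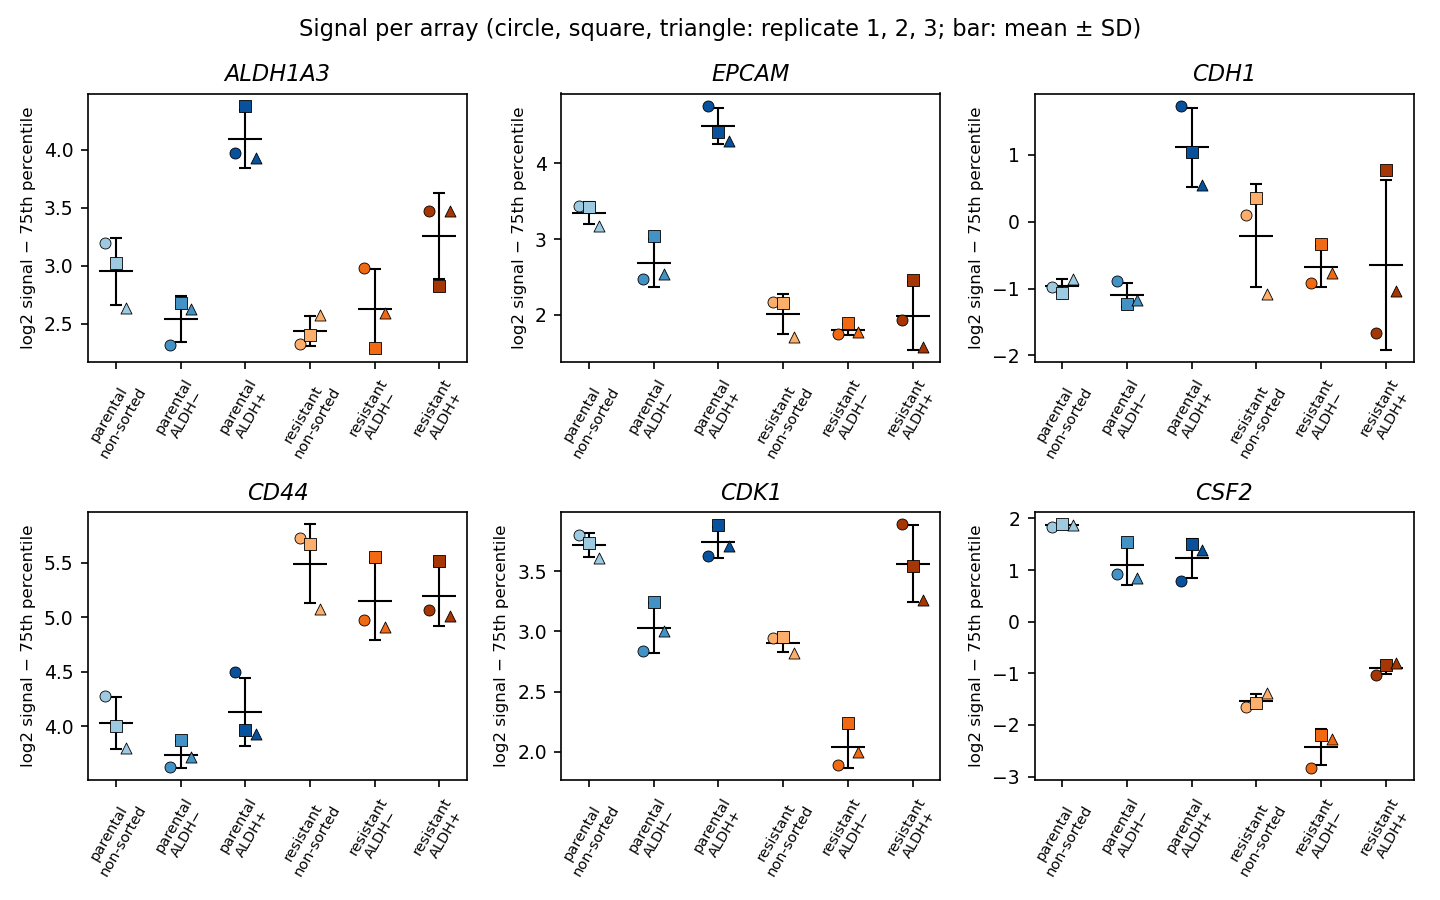
Log2 level of ALDH1A3, EPCAM, CDH1, CD44, CDK1 and CSF2 on each of the 18 arrays, relative to each array's 75th percentile, by group, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD (n = 3). ALDH1A3 and EPCAM rise from ALDH-negative to ALDH-positive parental cells (by 1.55 and 1.81), and CDK1 and CSF2 from ALDH-negative to ALDH-positive radioresistant cells (by 1.52 and 1.54).

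Cell cycle genes were higher as lists in ALDH-positive than in ALDH-negative radioresistant cells. Of 25 G1 to S genes 0 rose over all genes and 8 adjusted over the list alone, with a median of 0.37 and adjusted p = 2.01e-17 in camera (adjusted p = 0.470 with an estimated correlation). Of 27 G2 and M genes 1 rose over all genes, CDK1, and 9 adjusted over the list alone, with a median of 0.39 and adjusted p = 7.6e-15 in camera (adjusted p = 0.485 with an estimated correlation). RRM2 differed by 1.21 ± 0.26 (0.116 in limma), UHRF1, which maintains DNA methylation, by 0.63 ± 0.13 (0.113) and TTK by 0.90 ± 0.16 (0.0540). On slides 2 and 3 alone the medians were 0.518 and 0.565 for the G1 to S list and 0.699 and 0.535 for the G2 and M list, and without ALDH-negative replicate 3, ALDH-positive replicate 1 or ALDH-positive replicate 3 the latter was 0.17, 0.21 and 0.649. Of 33 double-strand break repair genes 0 rose over all genes and 5 adjusted over the list alone (median 0.125, adjusted p = 4.76e-05 in camera, adjusted p = 0.485 with an estimated correlation, 0.195 and 0.216 on slides 2 and 3 alone, 0.216 with median scaling), with RAD54L at 1.16 ± 0.27 (0.133 in limma) and BLM at 0.93 ± 0.24 (0.192). Of 20 NF-kappaB targets 1 rose, CSF2, and 3 adjusted over the list alone (median 0.42, adjusted p = 5.33e-08 in camera, adjusted p = 0.470 with an estimated correlation, 0.12 and 0.20 on slides 2 and 3 alone, 0.276 with normexp background), with CCL20 at 1.73 ± 0.43 (0.167 in limma) and CXCL1 at 1.22 ± 0.36 (0.278). The repair median was 0.0417, 0.0773 and 0.194 without ALDH-negative replicate 3, ALDH-positive replicate 1 or ALDH-positive replicate 2, and the NF-kappaB median 0.112, 0.719 and 0.247 without ALDH-negative replicate 1, ALDH-positive replicate 1 or ALDH-positive replicate 3. With the replicate block 3 G1 to S, 5 G2 and M and 1 double-strand break repair genes rose in limma.

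Ribosomal protein genes and genes of oxidative phosphorylation were lower as lists in ALDH-positive than in ALDH-negative radioresistant cells, with 0 of 28 and 0 of 26 members called by limma. Both lists had a median of -0.22 (-0.105 and -0.096 with quantile normalization, -0.132 and -0.131 with median scaling), with adjusted p = 4.76e-05 and 1.93e-04 in camera, and adjusted p = 0.767 and 0.577 with an estimated correlation in camera. RPL18 differed by -0.36 ± 0.15 (0.534 in limma) and RPL4 by -0.35 ± 0.15 (0.571). On slide 2 alone the ribosomal median was 0.05 and that of oxidative phosphorylation -0.09 (adjusted p = 0.305 in camera), against -0.48 and -0.36 on slide 3 alone, and without radioresistant ALDH-positive replicate 2 that p for the ribosomal list was 0.144 (median -0.116). Its median was -0.347 and -0.343 without ALDH-negative replicate 2 or ALDH-positive replicate 1. The replicate block added hypoxia and glycolysis genes (adjusted p = 0.0433 in camera against 0.0887 unblocked, and 0.807 with an estimated correlation), whose median was -0.20, or -0.396 on slide 2 alone and -0.0842 on slide 3 alone. Unblocked, that list passed camera without radioresistant ALDH-negative replicate 1 (0.0145) or 3 (0.0132), ALDH-positive replicate 2 (6.24e-06) or non-sorted replicate 3 (0.0484).

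No gene passed the test of whether the ALDH difference depended on the line: limma called 0, with 1012 at an unadjusted p under 0.05 and a smallest adjusted p of 0.156, and 1 without radioresistant ALDH-positive replicate 1. The interaction was -0.92 ± 0.31 for ALDH1A3 (0.694 in limma) and -1.63 ± 0.30 for EPCAM (0.180). As lists, epithelial genes had a median interaction of -0.66 (adjusted p = 1.02e-07 in camera, adjusted p = 0.128 with an estimated correlation) and basal prostate genes of -0.48 (0.0253 in camera, adjusted p = 0.295 with an estimated correlation). The parental ALDH-negative arrays lay on slide 1 and the parental ALDH-positive ones on slides 2 and 3, so a shift of slide 1 would also give an interaction. G1 to S and G2 and M genes both had a median of 0.21 (adjusted p = 4.83e-06 in camera, adjusted p = 0.931 with an estimated correlation). Without radioresistant ALDH-positive replicate 1 the G2 and M call was lost (0.0930 in camera) and the median turned to -0.0201. Without parental ALDH-positive replicate 2, radioresistant ALDH-negative replicate 1 or 3, or radioresistant ALDH-positive replicate 3 it was 0.367, 0.416, 0.0595 and 0.42. The G1 to S median was 0.138 without parental ALDH-negative replicate 2, 0.321 and 0.103 without radioresistant ALDH-negative replicate 2 or 3, and 0.34 without radioresistant ALDH-positive replicate 3. The basal call was lost in camera without parental ALDH-positive replicate 1 (0.0528), radioresistant ALDH-negative replicate 2 (0.165), or radioresistant ALDH-positive replicate 1 (0.0930) or 3 (0.0911, median -0.24), and the median was -0.726 without radioresistant ALDH-negative replicate 3. Median scaling moved the median of all genes in this contrast from -0.08 to 0.14, and those of the epithelial, basal, G1 to S and G2 and M lists to -0.44, -0.262, 0.429 and 0.431.

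Sorted cells, the mean of both ALDH populations, were compared with non-sorted cells of the same line. Limma called 0 genes in either line (1 without radioresistant ALDH-positive replicate 2). An unadjusted p under 0.05 was reached by 400 in the parental and 271 in the radioresistant line, below the 784 expected by chance in any comparison. Within slide 1 limma called 0 (460 at that p) between parental ALDH-negative and non-sorted arrays, and in the radioresistant line 0 (257) with slide as a block. In the parental line epithelial genes were higher as a list in sorted cells (median 0.16, adjusted p = 0.00246 in camera), and NF-kappaB targets lower (-0.25, 0.00246). Hypoxia and glycolysis genes (-0.17, 0.00461) and G2 and M genes (-0.12, 0.00844) were lower too, and with an estimated correlation each had an adjusted p = 0.973 in camera. The sorted populations went apart for the epithelial list, whose median against non-sorted cells was -0.169 in ALDH-negative and 0.391 in ALDH-positive cells, the latter on other slides, so the sorted mean does not stand for both. Both lay below non-sorted cells for NF-kappaB targets (-0.336 and -0.141), hypoxia and glycolysis (-0.0649 and -0.198) and G2 and M genes (-0.168 and -0.0914). Camera lost the parental NF-kappaB call with median scaling (0.0506) and without parental non-sorted replicate 3 (0.190). The epithelial median was 0.103 without parental non-sorted replicate 1 or ALDH-negative replicate 3. Camera lost the hypoxia call with median scaling (0.0739) and without parental non-sorted replicate 1 (0.0586, median -0.11) or ALDH-positive replicate 3 (0.0810). It lost the G2 and M call with median scaling (0.0739), with quantile normalization (0.0988) and without parental non-sorted replicate 1 (0.553, median -0.0268) or 2 (0.0544, -0.0672), ALDH-negative replicate 3 (0.123) or ALDH-positive replicate 3 (0.0810, -0.0756), and the median was -0.248 and -0.189 without non-sorted replicate 3 or ALDH-positive replicate 2. Median scaling moved the median of all genes from -0.01 to -0.13 in the parental sort contrast and those of the epithelial, hypoxia and G2 and M lists to 0.0374, -0.287 and -0.238, and quantile normalization that of the G2 and M list to -0.0642.

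In the radioresistant line ribosomal protein genes were higher as a list in sorted than in non-sorted cells (median 0.16, adjusted p = 1.4e-05 in camera, and -0.0078 with quantile normalization). G2 and M genes were higher too (0.19, adjusted p = 0.00231 in camera) and G1 to S genes lower (-0.16, 4.9e-04). With an estimated correlation each list had adjusted p = 0.625 in camera. The ribosomal median was 0.23 on slide 2 alone, where the call was lost (0.0665), and 0.16 on slide 3 alone, and 0.0966 and 0.0929 without non-sorted or ALDH-positive replicate 1. On slides 2 and 3 alone the G2 and M median was 0.54 and -0.27. The G1 to S median was 0.07 and -0.49, so both changed sign. Slide 3 held 1 non-sorted array. With slide as a block both calls were kept (medians 0.22 and -0.156, 6.5e-04 and 0.00942 in camera). Against non-sorted cells the G2 and M median was -0.0336 in ALDH-negative and 0.359 in ALDH-positive cells and the G1 to S median -0.381 and 0.0852, so neither list moved alike in both sorted populations, while the ribosomal median was 0.263 and 0.0525. Camera lost the G2 and M call without radioresistant non-sorted replicate 3 (0.747, median 0.0224), ALDH-negative replicate 1 (0.101, median 0.101) or ALDH-positive replicate 1 (0.315, median 0.071), and the G1 to S call without radioresistant non-sorted replicate 2 (0.338, median -0.0505), ALDH-negative replicate 3 (0.300, median -0.0859) or ALDH-positive replicate 3 (0.0890). Wnt target genes (-0.19, adjusted p = 0.00398 in camera), basal prostate genes (-0.23, 0.00809) and NF-kappaB targets (-0.17, 0.0264) were lower in sorted cells, with adjusted p = 0.373, 0.369 and 0.625 with an estimated correlation. Their medians were -0.31, -0.19 and -0.53 on slide 2 alone and -0.10, -0.40 and 0.00 on slide 3 alone. The Wnt call was lost on each slide alone (0.0665 and 0.440), as was the basal call (0.472 and 0.0886), and the NF-kappaB call on slide 3 (0.339), and all 3 were kept with slide as a block (0.00405, 0.0184 and 0.0264). With normexp background the basal and NF-kappaB medians were -0.0976 and -0.0581. In ALDH-negative and ALDH-positive cells the medians against non-sorted cells were -0.237 and -0.167 for Wnt targets, -0.177 and -0.248 for basal genes, and -0.531 and 0.0498 for NF-kappaB targets. The G2 and M median was 0.291 without non-sorted replicate 2, and without non-sorted replicate 3 the G1 to S and basal medians were -0.298 and -0.402. Camera lost the Wnt call without non-sorted replicate 3 (0.0865, median -0.123) or ALDH-negative replicate 1 (0.0815), and the basal call without non-sorted replicate 2 (0.0629, median -0.101), ALDH-negative replicate 3 (0.0860) or ALDH-positive replicate 3 (0.0890, median -0.143). It lost the NF-kappaB call without non-sorted replicate 3 (0.477, median -0.101), ALDH-negative replicate 1 (0.380), or ALDH-positive replicate 1 (0.319, median -0.0889) or 2 (0.0998), and the median was -0.26 without ALDH-negative replicate 3.

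The series title sets radioresistant beside progenitor cells, so the line difference in non-sorted cells was set against the ALDH difference in each line, pairs of comparisons that share no arrays and were part of 6 such relations computed. The changes of all tested genes correlated across genes, which are not independent replicates, at r = 0.190 (jackknife SE over the arrays 0.133; Spearman 0.193) with the parental ALDH difference. BMPER rose in both (by 1.36 in non-sorted radioresistant cells), and EPCAM was called in opposite directions. Genes that rose between the lines had a median parental ALDH difference of 0.07 and those that fell -0.05, with raw p = 0.0051 and 0.00459 and adjusted p = 0.00638 for both in camera, and adjusted p = 0.233 and 0.527 with an estimated correlation. Both of these comparisons run from slide 1 to slides 2 and 3. Without parental ALDH-negative replicate 2 or parental ALDH-positive replicate 1, r was 0.118 and 0.106. With the radioresistant ALDH difference the correlation was -0.127 (Spearman -0.124), and of its 8 called genes 5 were called between the lines, all 5 in the opposite direction. The 2 ALDH differences correlated at r = 0.0375 (Spearman 0.0569) and shared 0 called genes.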

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

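The tests of slide, of scan, of normalization and of whether a few genes carry the epithelial pattern were chosen only after the result was seen, although the slide and scan blocks and the normalizations had been set before as alternatives for the counts; those of 1 pair of arrays, of 1 array and of other splits of the samples were set before.

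At camera's preset correlation 6 gene lists passed the test of whether the ALDH difference depended on the line, which singled them out. The parental part of that contrast sets slide 1 against slides 2 and 3, so a shift of slide 1 was not excluded. The interaction had a camera adjusted p of 1.02e-07 for epithelial genes, 4.83e-06 for G1 to S genes, 4.83e-06 for G2 and M genes, 0.0253 for basal prostate genes, 0.0452 for double-strand break repair genes and 0.0499908 for NF-kappaB targets. With an estimated correlation the adjusted p was 0.128, 0.931, 0.931, 0.295, 0.931 and 0.954 in camera. The repair call was lost with quantile normalization (0.0604) and without parental ALDH-negative replicate 2 (0.0917), parental ALDH-positive replicates 1 (0.0670, median 0.0428) or 3 (0.146), radioresistant ALDH-negative replicate 3 (0.458, 0.0143) or radioresistant ALDH-positive replicate 1 (0.225, 0.0267), and the median was 0.0564 without radioresistant ALDH-negative replicate 2. Median scaling moved the repair median from 0.0884 to 0.31 and the NF-kappaB median from 0.227 to 0.448, and normexp the latter to 0.112. The NF-kappaB call was lost with median scaling (0.257), quantile normalization (0.0604) and normexp background (0.0718). It was also lost in camera without 9 of the arrays: parental non-sorted 1 (0.0545) and 3 (0.0507), ALDH-negative 2 (0.164, median 0.0784) and 3 (0.295, 0.0721) and ALDH-positive 1 (0.183, 0.0711) and 2 (0.0691), and radioresistant ALDH-negative 1 (0.637, 0.00703) and ALDH-positive 2 (0.0510) and 3 (0.686, 0.00178). Its median was 0.43, 0.354, 0.524 and 0.486 without parental ALDH-negative 1, parental ALDH-positive 3, radioresistant ALDH-negative 3 or radioresistant ALDH-positive 1. The G2 and M call was lost without radioresistant ALDH-positive 1 (0.0930), where the median turned from 0.21 to -0.0201, and the basal call without parental ALDH-positive 1 (0.0528), radioresistant ALDH-negative 2 (0.165) or radioresistant ALDH-positive 1 (0.0930) or 3 (0.0911).

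Probes without a gene symbol, which no comparison in the report used, changed between the lines. Of 9226 that passed the detection filter, limma called 924 (10%) in non-sorted, 838 (9.08%) in ALDH-negative and 747 (8.1%) in ALDH-positive cells. It called 0 in either ALDH comparison and in the radioresistant sort comparison, 5 in the parental sort comparison and 1 for the interaction.

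The largest pattern was the line difference of 4593, 4866 and 4094 genes in non-sorted, ALDH-negative and ALDH-positive cells. Slide was tested where both lines shared slides: with slide as a block limma called 3337 genes in ALDH-positive cells, 3208 of them among the 4094, and 97.4% of the genes called in non-sorted and 97.3% of those called in ALDH-negative cells had the same sign there, which argues against slide as the main cause. The changes on slides 2 and 3 alone correlated across genes at 0.55. Normalization is argued against by a smallest count of 3831 over 3 scalings and 3 populations. All parental non-sorted and ALDH-negative arrays lay alone on scan 1. In ALDH-positive cells scan as a block gave 491 genes, where 2 of the 3 radioresistant arrays had their own scan. Parental ALDH-positive arrays shared scans with radioresistant arrays of other populations. Within those scans 97% of the genes called in non-sorted cells kept their sign between radioresistant ALDH-negative and parental ALDH-positive arrays, and 98.4% of those called in ALDH-negative cells between radioresistant non-sorted and parental ALDH-positive arrays. Of the genes called in ALDH-positive cells 97.8% kept their sign in non-sorted cells, with no array on the scan of those 2. Outside the scan fits no array was shared in these 3 tests, which argue against scan as the main cause. What stays open is biology the design names, the selection by irradiation, and any difference between cultures grown apart, which was not tested.

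In the radioresistant line 52 cell cycle genes had a median of 0.382 between ALDH-positive and ALDH-negative cells, and 88.5% lay above 0. The medians were 0.571 and 0.556 on slides 2 and 3, each with 1 array in 1 group. Those of the pairs were 0.523, 0.308 and 0.413, and the lowest of 3 scalings 0.347. These argue against slide, 1 pair and normalization as the whole cause. Scan is not excluded: only pair 1 shared a scan, and 2 ALDH-positive arrays had their own. A hypothesis left open is that ALDH-positive radioresistant cells may hold more cycling cells, which was not measured. Genes of a cycle list move together, and with an estimated correlation the adjusted p was 0.470 and 0.485 in camera.

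In the parental line all 21 tested epithelial genes (100%) lay higher in ALDH-positive cells, with a median of 0.521. The pair medians were 0.86, 0.47 and 0.38, and the highest adjusted p without 1 of the 6 arrays was 1.8e-11 in camera, so neither 1 array nor a few genes carry the pattern. Slide cannot be told apart from the ALDH population here, because the 3 ALDH-negative arrays lay on slide 1 and the ALDH-positive ones on slides 2 and 3. A shift of slide 1 against the others could also give the small line medians of 0.12 and 0.10 in ALDH-negative and non-sorted cells beside -0.55 in ALDH-positive cells, if epithelial genes were lower in the radioresistant line.

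Splits of the 3 against 3 arrays number 10, the real one included, too few for a share under 0.05. For the line comparisons 1 of 10 splits, the real one, gave as many genes as the 4593, 4866 and 4094 observed, and the highest other gave 0, 0 and 2. For the parental ALDH comparison 1 of 10 gave as many as the real 4, and the highest other gave 0. For the radioresistant ALDH comparison 2 of 10 gave as many as the real 8: the other, with 116 genes, parted exactly the arrays of slide 2 from those of slide 3, which points to a structure of the samples, and slide as a block left 2 genes. Among the 4 splits that part all 3 pairs, as the real split does, the highest other gave 0.

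For the interaction (100 drawn splits) and both sort comparisons (84 splits each) the real count was 0, which every split reaches whatever the data, so these counts decide nothing about chance. The highest other was 23 for the interaction. In the parental sort comparison, the highest other, 17 genes, parted the 3 ALDH-positive arrays from the rest, and that in the radioresistant line, 1806 genes, parted the 3 arrays with replicate number 3, a structure of the samples that the numbers follow.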

How the results depend on the processing

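The slides alone, the block for each replicate number within each line, the replicate and slide blocks together, and median scaling and normexp for the gene lists were tests chosen after the result was seen. The counts of genes changed between the lines kept within 1.5 times of 4593, 4866 and 4094 under median scaling, quantile normalization, normexp background and the deposited table. In ALDH-positive cells the count was 491 with scan as a block, 1891 with only the groups compared, 54 on slide 2 (1 array of each line) and 904 on slide 3 (2 of each). A threshold of at least 2-fold gave 1526, 1585 and 1364. The counts of the ALDH comparisons ran from 0 to 12 in the parental and from 0 to 200 in the radioresistant line. In the parental line (4) they were 0 with median scaling, 7 with quantile normalization, 12 with normexp background, 8 with detection on all 18 arrays, 10 with the mean of probes, 9 with slide as a random block, 1 with only the groups compared and 7 with a variance trend and robust fit. In the radioresistant line (8) they were 5 with median scaling, 27 with quantile normalization, 4 with no detection filter, 13 with detection on all 18 arrays, 2 with slide as a block, 0 with scan as a block, 0 with only the groups compared, 17 with a variance trend and robust fit, 5 at 2-fold or more, 0 on slide 2, 0 on slide 3 and 0 with the replicate and slide blocks together. The cause was not tested.

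With the replicate number as a block the counts were 12 in the parental and 78 in the radioresistant ALDH comparison, 1 in the parental sort comparison, and 5618, 5815 and 5100 in the line comparisons, where not all pairs met the limit for pairing although the deviations of arrays numbered 3 correlated between the lines at 0.23, 0.21 and 0.20. With a block for each number within each line the ALDH counts were 0 and 200. Among the lists the replicate block ended the NF-kappaB call in ALDH-positive cells between the lines (camera adjusted p = 0.0667), added 3 lists in the parental and 1 in the radioresistant ALDH comparison, and added Wnt pathway components between sorted and non-sorted radioresistant cells (camera adjusted p = 0.0427 against 0.0632). It changed no other list call, and no other count of genes by over 1.5 times.

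Leaving out each array in turn gave 3173 to 4152 genes for the line comparison in non-sorted, 3652 to 4337 in ALDH-negative and 2814 to 4000 in ALDH-positive cells. It gave 0 to 6 for the parental and 1 to 14 for the radioresistant ALDH comparison, 0 to 1 for the interaction, 0 to 0 for the parental and 0 to 1 for the radioresistant sort comparison. The 41 list calls at the preset correlation became 2 with an estimated correlation, and between 36 and 47 without 1 array. The correlation of the line change with the parental ALDH difference, 0.190, ran from 0.106 to 0.254 without 1 array. For named genes, 7741 of 8464 called pairs of gene and alternative kept their call, 723 lost it and 0 reversed. For 6 pairs of list and alternative the median of a called list reversed: the G2 and M interaction (0.21) without radioresistant ALDH-positive replicate 1 (-0.0201; -0.0201 to 0.42 without 1 array), ribosomal genes between sorted and non-sorted radioresistant cells with quantile normalization (-0.0078), ribosomal genes in the radioresistant ALDH comparison on slide 2 (0.0501), and, between sorted and non-sorted radioresistant cells, G1 to S genes on slide 2 (0.0742), G2 and M genes on slide 3 (-0.267) and NF-kappaB targets on slide 3 (0.00263). Signal over background limits dim genes: 14138 of the 15687 tested genes were well above background on all arrays, and the folds of the others rest on bounds or on part of the arrays.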

Other observations

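The tests of copy number and of local co-regulation were written before their result was seen; the stretches named after them were picked after it.

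Stress and signalling genes not described so far also differed between non-sorted cells of the lines, with no list among them passing camera. NUPR1, a stress-induced chromatin protein, rose by 4.46 ± 0.58, and of 22 genes of the unfolded protein and ATF4 response 6 rose and 1, DDIT3, fell, at -1.53 ± 0.26 (limma, 3 arrays per group). That list had an adjusted p of 0.0802 in camera, or 0.0144 and 0.0299 without parental or radioresistant non-sorted replicate 3. Of 23 p53 target genes 8 rose and 5 fell (0.673 in camera), among them PHLDA3, which restrains AKT, up by 1.68 ± 0.17, and CDKN1A, the cell cycle inhibitor p21, which changed by -1.08 ± 0.23. Of 24 interferon genes 4 rose and 6 fell (0.761 in camera), with IFIT2 up by 1.51 ± 0.27 and MX1 at -1.72 ± 0.33. The chaperone HSPA1A changed by -2.98 ± 0.19, while the small heat shock protein HSPB1 rose by 1.26 ± 0.25.

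Of 20 tested TGF-beta and BMP genes 4 rose and 3 fell in non-sorted radioresistant cells, of 17 Notch genes 6 rose and 4 fell, and of 10 hedgehog genes 4 rose and 0 fell, and no such list passed (adjusted p = 0.384, 0.789 and 0.145 in camera). The growth factor BMP7 was at least 12-fold lower there, while BMP4 rose by 3.42 ± 0.47 (above background on 1 of 3 parental arrays) and the BMP target ID3 by 1.22 ± 0.19. The receptor NOTCH3 rose by 2.25 ± 0.24 and the glycosyltransferase MFNG, which modifies Notch receptors, by 1.44 ± 0.22, while the ligand JAG2 changed by -1.40 ± 0.22. GLI3, a transcription factor of the hedgehog pathway, rose by 3.27 ± 0.58 (2 of 3 parental arrays). Of the Wnt antagonists DKK3 rose by 2.99 ± 0.36 and SFRP1 changed by -1.78 ± 0.25. TGM2, transglutaminase 2, changed by -2.23 ± 0.30, and of 24 hypoxia and glycolysis genes 0 rose and 6 fell, with the glycolytic enzyme PFKP at -0.88 ± 0.16.

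Neighbouring genes shifted together between the lines. Ordered along the chromosomes of GRCh38.p14, the changes in non-sorted cells of genes next to each other correlated at 0.167 across genes, which are not independent replicates, and those of genes 20 places apart at 0.0838, against at most 0.0313 and 0.0332 in 1000 shuffles. At 20 places apart the value was 0.0936 in ALDH-negative and 0.0785 in ALDH-positive cells. A candidate explanation is that copy number differences between the lines may move long stretches of genes, since co-regulation of adjacent genes only would leave no relation at 20 places. Part of the relation arises without a line difference: the parental ALDH comparison had 0.108 between neighbours, 0.0313 at 20 places (shuffles at most 0.0257) and 0.0487 at 50, the last against 0.0578 for the line in non-sorted cells, and the radioresistant one had 0.083, 0.0225 (at most 0.0247) and 0.0132. The relation alone therefore does not show copy number differences. No DNA was measured in the arrays used here.

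Of 511 stretches of 30 genes, 4 had a median change beyond all 1000 shuffles in each of the 3 populations. CNTN6 to RPUSD3, CIDEC to IQSEC1 and NUP210 to RAB5A, which follow each other in gene order, were higher in the radioresistant line, with medians of 0.83, 0.80 and 0.99 in non-sorted, 0.86, 0.85 and 0.84 in ALDH-negative and 0.94, 0.74 and 0.76 in ALDH-positive cells. TTC33 to MOCS2 was lower, at -0.75, -0.84 and -0.72, and the stretch before it, SUB1 to PTGER4, was beyond the shuffles in 2 populations. These stretches were chosen after their values were seen, and a gain or a loss there is a hypothesis that DNA would have to test.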
